A study of Mus musculus with 6 samples.

How the data were processed

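The series holds 6 RNA-seq libraries from the vomeronasal organ of male CD-1 mice, 3 after pup exposure and 3 after a control exposure. Per the labels' protocols, lysates were immunoprecipitated with an antibody to phosphorylated ribosomal protein S6, cDNA was made with a low-input template-switching kit, and the DNA was sheared before sequencing. The deposited table holds whole-number read counts per Ensembl gene and library, not normalized. The genome build is GRCm38 per the submitters' processing notes; the aligner, the counting tool, its treatment of reads that map to several places, and the annotation release are not given in the sources used here. No library of unprecipitated input RNA was analysed here, so enrichment over the tissue's own RNA was not measured, and a difference in the precipitate can come from RNA abundance, from ribosome loading or from the share of S6 that was phosphorylated. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Replicates were compared before use: within a group, every pair differed far beyond sampling noise (chi-square per degree of freedom 94.8 to 345), so none was counted as a duplicate.

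Gene IDs were named from GENCODE M21, in which 36639 of the 38561 IDs matched; the other 1922 kept their ID and held 0.172% to 0.233% of the counts of a library. Trpc2 had been chosen beforehand as a named gene and was not matched to a row. Total counts were 10590716 to 11240065 after control exposure and 18199476 to 20871266 after pup exposure. The 292 named vomeronasal and formyl peptide receptors had 12999 to 89633 counts per library. Obp2a, a secreted odorant-binding protein, was the most abundant gene in every library, with 9.38% to 26.0% of counts, and TMM factors ran from 0.605 (control exposure replicate 3) to 1.39 (pup exposure replicate 2). On the first principal component (35.1% of variance) pup exposure replicate 1 stood apart, and on the second (25.6%) control exposure replicate 3 and pup exposure replicate 2 lay at opposite ends.

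The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with an intercept and the group. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The common biological coefficient of variation was 0.535. Values given as CPM are read counts relative to library size, scaled by TMM factors, standard errors were derived from the F statistic, and log2 fold changes are pup exposure over control exposure. Counts of receptors were made both over all genes and over V1R, V2R and formyl peptide receptors alone. Gene lists with at least 3 tested members were tested together with camera from limma 3.58.1 at a preset correlation of 0.01, and also with an estimated correlation and with fry. A total of 24 lists was fixed, of which 22 had enough tested members. Shares of counts were compared by exact permutation tests, two-sided, which for 3 against 3 libraries cannot give a p below 0.1.

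Genes named in the text followed a rule fixed before the data were examined, as were the lists, the design and the other settings first listed. The rule took the 12 genes with the smallest p past the threshold in each direction with separated groups, and where fewer than 5 passed, the 5 with the smallest unadjusted p. It also took receptors past the threshold over all genes or over their list, the 5 receptors with the smallest p in each direction where fewer than 5 passed, up to 4 members of each list, and 11 genes named in advance (Fos, Egr1, Arc, Junb, Rps6, Trpc2, Omp, Gnai2, Gnao1, Vmn2r65 and Vmn2r88). Vmn2r65 and Vmn2r88 were recalled from published work on male responses to pups and are not an independent choice. Not every gene that the rule allows is named. Outside the rule, Per1, Nr4a3 and the genes of the first paragraphs of the closing observations were named after their values were seen, and Obp2a as the most abundant gene.

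Those settings were RLE and upper quartile scaling, library totals only, no filter, a stricter filter (at least 1 CPM in 3 libraries and 50 counts in all), DESeq2 1.42.0, limma-voom with and without sample quality weights, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were thinning every library to 10590716 counts, a fit on the receptors alone, receptor enrichment among genes at an unadjusted p under 0.05, and receptor enrichment in DESeq2 without the genes that lack an adjusted p. A first look at the edgeR results was taken before these additions and before the tests of explanations were written down.

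To see how far receptors can share reads, each gene's longest transcript in GENCODE M21 was cut into words of 50 bases, and words found in a transcript of another gene on either strand were counted. No genome sequence was used, so copies outside annotated transcripts were not seen, and CD-1 mice differ from the reference strain. The tests were run on simulated data with 15498 genes, of which 200 were drawn to change by a known fold. Of changed genes that could be tested, edgeR called 0 of 48 at 2-fold, 10 of 47 at 4-fold, 31 of 47 at 8-fold and 43 of 48 at 16-fold, with 4 false calls, and DESeq2 called 1, 23, 34 and 43, with 28 false calls. Camera called a list of 20 genes raised 2-fold and 0 of 20 random lists. Simulated genes were drawn independently of each other, so this does not show how often camera errs where members vary together.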

Results

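RNA bound to ribosomes carrying phosphorylated ribosomal protein S6 was collected from the vomeronasal organ of male CD-1 mice, an outbred stock, and sequenced. The vomeronasal organ is the sensory epithelium of the nose that detects pheromones, and phosphorylation of S6 rises in neurons that have recently been active, so that RNA pulled down with an antibody to phosphorylated S6 is enriched for active cells. The labels give 3 libraries after pup exposure and 3 after a control exposure whose nature they do not describe. The control exposure libraries held 11240065, 10617461 and 10590716 counts and the pup exposure libraries 18199476, 20401434 and 20871266 counts, so depth was separated by group (exact permutation test, two-sided, p = 0.1, the smallest p that 3 against 3 libraries allow). Of 38561 genes in the table, 23900 had a count and 15498 were tested.

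The comparison asked which vomeronasal receptors, and so which sensory neurons, were more or less represented after males met pups. Among 195 vomeronasal and formyl peptide receptors tested, Vmn2r88 and Vmn2r65 were higher and Vmn2r116 was lower after pup exposure. All 3 belong to the V2R family, receptors of basal vomeronasal neurons. Vmn2r88 went from 60.9 ± 4.99 CPM (SD, n = 3) after control exposure to 529 ± 148 CPM (SD, n = 3) after pup exposure, a fold of 8.68. Vmn2r65 went from 15.7 ± 10.9 to 115 ± 45.5 CPM (SD, n = 3 each), a fold of 7.35, and Vmn2r116, known as the receptor of a peptide in male tears, went from 120 ± 39.5 to 10.8 ± 7.54 CPM (SD, n = 3 each). For each of the 3 genes every pup exposure library lay on the same side of every control exposure library.

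In edgeR's quasi-likelihood test the log2 fold change of Vmn2r88 (ENSMUSG00000000606) was 3.12 (SE 0.41), with a Benjamini-Hochberg adjusted p of 0.00138 adjusted over the receptor list alone and 0.0938 over all genes tested. For Vmn2r65 (ENSMUSG00000066372) the log2 fold change was 2.88 (SE 0.60), with edgeR adjusted p = 0.0282 over the receptor list alone and 0.354 over all genes. The log2 fold change of Vmn2r116 (ENSMUSG00000090966) was -3.47 (SE 0.55), with edgeR adjusted p = 0.00415 over the receptor list alone and 0.105 over all genes. Over all genes, then, 0 receptors passed the threshold of 0.05 in either direction in edgeR, while 18 receptors were higher and 9 lower at an unadjusted p under 0.05. Over all genes DESeq2 called 5 receptors higher and 2 lower, limma-voom 1 and 1. Vmn2r88 and Vmn2r65 had been named beforehand from published work on male responses to pups, so their selection was not independent of these samples. The call of Vmn2r65 over the receptor list was lost when control exposure replicate 1 (log2 fold change 2.44, edgeR adjusted p = 0.0572), control exposure replicate 3 (2.88, adjusted p = 0.137), pup exposure replicate 2 (2.64, adjusted p = 0.0831) or pup exposure replicate 3 (2.81, adjusted p = 0.0833) was left out. With library sizes, scaling and spread taken from the receptors alone, an alternative chosen after seeing the data, Vmn2r88 (log2 fold change 2.98, SE 0.64) and Vmn2r65 (2.72, SE 0.57) both had an edgeR adjusted p of 0.0671, and Vmn2r116 (-3.69, SE 0.60) one of 0.0273.

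Within the V2R family, the share of counts held by Vmn2r88 was 4.28% ± 1.07 (SD, n = 3) after control exposure and 30.1% ± 6.98 (SD, n = 3) after pup exposure. The share held by Vmn2r65 was 1.02% ± 0.604 and 6.30% ± 1.43, and that of Vmn2r116 was 8.14% ± 2.53 and 0.581% ± 0.340 (SD, n = 3 each). Each of the 3 shares separated the groups completely (exact permutation test, two-sided, p = 0.1, the smallest the design allows).

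On the GRCm38 build, the GENCODE M21 annotation places Vmn2r88 on chromosome 14 from 51410820 to 51420721 (plus strand). It places Vmn2r65 on chromosome 7 from 84935565 to 84964115 (minus strand) and Vmn2r116 on chromosome 17 from 23384604 to 23404422 (plus strand), all as protein-coding genes. Receptor genes lie in clusters of close relatives, and reads from shared stretches can be split between them. Of the 50-base words of the annotated transcript, 0.30% in Vmn2r65, 16.6% in Vmn2r88 and 13% in Vmn2r116 also occurred in a transcript of another gene. Vmn2r-ps159, a pseudogene that holds 7.60% of the words of Vmn2r88, went from 16.6 ± 3.05 to 59.0 ± 20.3 CPM (SD, n = 3 each), and was the 1 of 24 tested receptor pseudogenes past the threshold adjusted over the list alone.

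**Figure D1:**
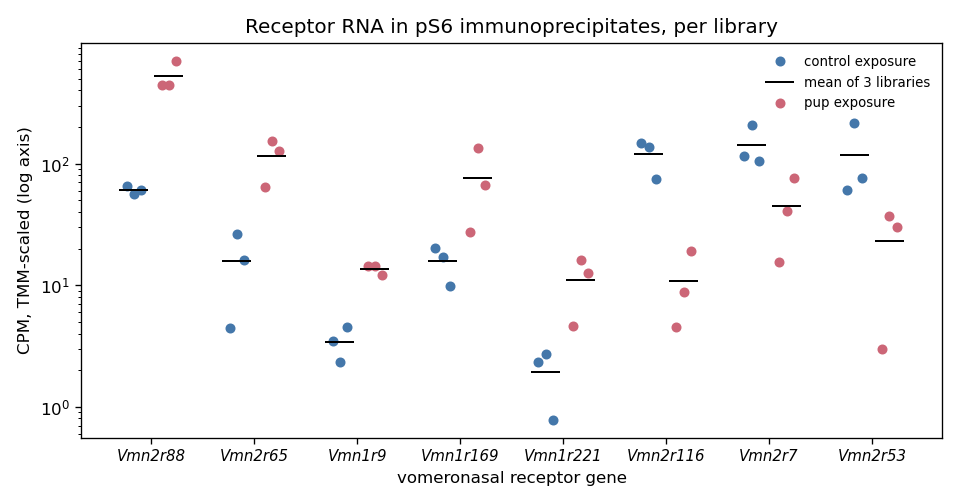
CPM of 8 vomeronasal receptor genes in each library on a log axis, scaled by TMM, with blue points for control exposure, red points for pup exposure and a line at the mean of 3 libraries. Vmn2r88 lay at 56.0 to 66.0 CPM after control exposure and at 442 to 700 CPM after pup exposure, and Vmn2r116 at 74.9 to 149 CPM and at 4.56 to 19.2 CPM.

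The V1R family, the receptors of apical vomeronasal neurons, had 94 tested members, and 0 passed in either direction when adjusted over the receptor list alone. The V1R genes with the smallest p were Vmn1r9 (log2 fold change 1.99, SE 0.47) and Vmn1r169 (2.27, SE 0.55), each with an edgeR adjusted p of 0.0533 over the receptor list, and Vmn1r221 (2.49, SE 0.66, adjusted p = 0.0904). DESeq2 called these 3 genes higher over all genes, and Vmn1r169 and Vmn1r221 passed over the receptor list without pup exposure replicate 1 (adjusted p = 0.00837 and 0.0171). Of the 97 V2R genes tested, 2 were higher and 1 lower over the receptor list, and 69 had a positive and 28 a negative log2 fold change. Other V2R genes with a negative log2 fold change and small p were Vmn2r53 (log2 fold change -2.34) and the family C receptors Vmn2r7 (-1.69) and Vmn2r6 (-1.37), with edgeR adjusted p between 0.163 and 0.210 over the receptor list. DESeq2 called Vmn2r53 over all genes (adjusted p = 0.0496) and Vmn2r53 (0.0169) and Vmn2r7 (0.0319) over the receptor list, and edgeR without a filter called all 3 over the receptor list. The log2 fold change of Vmn2r53 was -1.55 without control exposure replicate 2. As a set, the V1R list had a median log2 fold change of 0.25 and a camera adjusted p of 0.263, and the V2R list a median of 0.23 and a camera adjusted p of 0.234. Without pup exposure replicate 1 both lists passed (camera adjusted p = 0.0171 for V1R and 0.0129 for V2R, medians 0.55 and 0.39), while the V1R median was -0.018 without control exposure replicate 1 and -0.029 without pup exposure replicate 2. With single libraries left out the V2R median ran from 0.028 to 0.39 and its camera adjusted p from 0.0129 to 0.996. In the mixed form of limma's fry test, which asks whether members change in either direction, 5 lists passed: V2R receptors (adjusted p = 0.00242), family C V2R receptors (0.0290), mature vomeronasal neurons (0.0113), olfactory receptors (0.0204) and progenitors and immature neurons (0.0317).

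Family C V2R receptors, which are shared by many basal neurons, split within their list. Adjusted over the list alone, Vmn2r5 and Vmn2r3 were higher and Vmn2r7 and Vmn2r6 lower among 7 members. Of the words of Vmn2r5, Vmn2r6 and Vmn2r7, 43.6%, 49.0% and 51.6% were shared with other genes, so their counts are uncertain. The list's median log2 fold change was 0.39, and -0.22 without pup exposure replicate 2, while its camera test pointed down with all libraries (adjusted p = 0.864). Formyl peptide receptors, which detect bacterial and mitochondrial peptides, had 4 tested members with a median log2 fold change of -1.45 (camera adjusted p = 0.0965). With single libraries left out that median ran from -1.98 to -0.64, and the list passed without pup exposure replicate 2 (median -1.98, adjusted p = 0.0364) and with library totals only (-1.04, 0.0385). Among these 4, Fpr3 had the smallest p, with a log2 fold change of -2.41 (SE 1.0), and -1.52 without control exposure replicate 2.

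The families took small shares of each library. V1R genes held 0.0693% ± 0.0208 of all counts after control exposure and 0.111% ± 0.0439 after pup exposure (SD, n = 3 each; exact permutation test, two-sided, p = 0.2). V2R genes held 0.141% ± 0.0606 and 0.202% ± 0.0701 (SD, n = 3 each; exact permutation p = 0.5). Formyl peptide receptors held 0.00199% ± 0.00144 and 0.000914% ± 0.000628 (SD, n = 3 each; exact permutation p = 0.4), and the ratio of 0.460 between them became 0.788 without control exposure replicate 2. In each family the values of the groups overlapped. With the 50 most abundant genes left out, the exact permutation p was 0.2 for each family. This test cannot give a p below 0.1 here, so it could not have passed 0.05 and does not show that the shares were equal.

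Over all genes, edgeR's quasi-likelihood test called 0 genes higher and 0 lower after pup exposure at an adjusted p of 0.05, with a smallest adjusted p of 0.0938. At an unadjusted p under 0.05, 978 genes were higher and 723 lower. DESeq2 called 50 genes higher and 77 lower, limma-voom 1 and 7, limma-voom with sample quality weights 1 and 11, and edgeR without a filter on low counts 61 and 59. In 1573 genes every pup exposure library lay above every control exposure library, and in 1488 below. Together these were 19.8% of genes tested, where chance gives 10% on average over splits. Genes vary together and the share was not computed for other splits, so its spread by chance is not known. Depth was also separated by group, so the excess cannot be credited to exposure. Of the 978 genes higher at an unadjusted p under 0.05, a set used because no gene passed and chosen after seeing the data, 18 were receptors (odds ratio 1.52, Fisher's exact test, two-sided, p = 0.101). Among genes higher at an adjusted p under 0.05, receptors were 5 of 50 in DESeq2 (odds ratio 10.8, Fisher's exact p = 0.000164) and 4 of 61 in edgeR without a filter (6.81, p = 0.00366), both against all genes with a count. DESeq2 gave no adjusted p for 11599 of these genes, and with them left out, a choice made after seeing the data, its odds ratio was 10.43 (Fisher's exact p = 0.000204). On simulated data DESeq2 made 28 false calls and edgeR 4, so the DESeq2 set may hold more false calls than its threshold states. Those counts were drawn once with edgeR's own spread estimates on the 15498 genes tested, which may favour edgeR. On the real data DESeq2 was run on all 23900 genes with a count. Fisher's test also takes genes as independent, which receptors that share reads are not. In limma-voom, with and without sample quality weights, the 1 gene called higher was Vmn2r88, too few for a test of enrichment.

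The lower genes with the smallest p were Zfp36l1, Pigb, Arl5b and S1pr1, each with an edgeR adjusted p of 0.0938 and so not past the threshold. Zfp36l1, an RNA-binding protein that promotes mRNA decay, went from 1162 ± 313 to 82.3 ± 50.1 CPM (SD, n = 3 each; log2 fold change -3.82, SE 0.54). Pigb, an enzyme of membrane anchor synthesis, had a log2 fold change of -2.55 (SE 0.39), Arl5b, a small GTPase, -2.90 (SE 0.44), and S1pr1, a receptor for a signalling lipid, -2.34 (SE 0.36). These 4 genes passed in DESeq2 and limma-voom. Behind Vmn2r88, the higher genes with the smallest p outside the receptors were Rnf144b, a ubiquitin ligase (log2 fold change 2.63, SE 0.48, edgeR adjusted p = 0.199), Mbnl3, a splicing regulator (3.69, SE 0.79, adjusted p = 0.354), and ENSMUSG00000093785 (2.18, SE 0.47, adjusted p = 0.354). These 3 passed in DESeq2 (adjusted p = 0.000309, 0.00151 and 0.00663) and in edgeR without a filter, and not in limma-voom.

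Immediate early genes, which neurons transcribe within minutes of activity, had a positive log2 fold change in 21 of 27 tested members, with a median of 0.58 (0.33 without pup exposure replicate 1). Fosl2 (1.30, SE 0.41), Egr1 (1.19, SE 0.38), Jun (1.0, SE 0.37) and Btg2 (1.14, SE 0.44) had the smallest p, none past the threshold over all genes or over the list alone. At an unadjusted p under 0.05, 4 members were higher and 2 lower, the lower being Per1 (-1.29, SE 0.57) and Nr4a3 (-1.13, SE 0.51). Fos had a log2 fold change of 0.58 (SE 0.35). Junb had one of 1.19 (SE 1.01), with 0.59 without control exposure replicate 1 and 2.02 without control exposure replicate 2. Arc had one of -0.090 (SE 0.55), which turned to 0.16 with library totals only, 0.071 without control exposure replicate 2 and 0.33 without pup exposure replicate 1. As a list the immediate early genes missed the threshold in limma's camera test with a preset correlation (adjusted p = 0.0594, and adjusted p = 0.487 with an estimated correlation). The list passed in the same test with library totals only (adjusted p = 0.0350), without a filter (0.0188) and with limma-voom (0.0373). It also passed when control exposure replicate 2 (0.0163), control exposure replicate 3 (0.0304), pup exposure replicate 1 (0.0416) or pup exposure replicate 2 (0.0364) was left out, within a range of 0.0163 to 0.487 over all alternatives.

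Of 22 lists tested, 2 passed camera with the preset correlation, both lower. The H2-Mv genes, non-classical MHC genes of V2R neurons, had a negative log2 fold change in 8 of 9 members with a median of -1.08 (camera adjusted p = 0.00798). With an estimated correlation their camera adjusted p was 0.524. H2-M10.4 (-1.44, SE 0.47), H2-M1 (-1.18, SE 0.44), H2-M9 (-1.52, SE 0.65) and H2-M11 (-1.40, SE 0.69) had the smallest p in the list. Red blood cell genes were negative in 4 of 4 members with a median of -1.50 (camera adjusted p = 0.00769, and 0.487 with an estimated correlation), and the haemoglobin chains Hbb-bs (-1.75, SE 0.55) and Hba-a1 (-1.56, SE 0.52) were lower adjusted over the list alone. Without control exposure replicate 3 Hba-a1 was at -0.99, and without control exposure replicate 1 H2-M10.4 was at -0.93. With an estimated correlation, then, 0 lists passed. Without control exposure replicate 1 the H2-Mv median was -0.56 (camera adjusted p = 0.145), and 1 list passed. With other single libraries left out, 5 to 8 lists passed in 4 of the fits: 7 without control exposure replicate 2, 5 without control exposure replicate 3, 8 without pup exposure replicate 1 and 5 without pup exposure replicate 2.

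Markers of other cell types of the organ were counted in the same libraries. Sustentacular cell markers had a median of -0.66 (camera adjusted p = 0.0718), with Cbr2, a carbonyl reductase, at 3030 ± 178 and 1237 ± 315 CPM (SD, n = 3 each), and Cyp2g1, a cytochrome of the olfactory mucosa (log2 fold change -2.70, SE 0.94). Both were lower adjusted over the list alone. The values of Cyp2g1 overlapped between groups, at 56.4, 1.26 and 14.4 CPM after control exposure and 3.11, 5.56 and 2.42 CPM after pup exposure, and its log2 fold change was -1.05 without control exposure replicate 1 and -0.13 in limma-voom with sample quality weights. The sustentacular list passed without control exposure replicate 2 (median -0.60, camera adjusted p = 0.0163). Its members Cyp2a5 (-0.66, SE 0.37) and Krt18 (-0.68, SE 0.41) were not past the threshold over the list alone. With single libraries left out Cyp2a5 ran from -0.90 to -0.53 and Krt18 from -0.87 to -0.42. Immune cell markers had a median of -0.28 (camera adjusted p = 0.0718), and the MHC class II genes H2-Ab1 (-1.53, SE 0.45), H2-Aa (-1.06, SE 0.43) and Cd74 (-1.04, SE 0.45) had the smallest p, none past the list alone, and lay at -0.98, -0.78 and -0.60 without control exposure replicate 1. The immune list passed without control exposure replicate 2 (median -0.36, camera adjusted p = 0.0346), without pup exposure replicate 1 (-0.72, 0.00900), with sample quality weights (-0.56, 0.0494) and with the replicate number as a block (-0.63, 0.0404). Gland and secretory transcripts took 42.3% ± 11.9 of all counts after control exposure and 37.2% ± 9.56 after pup exposure (SD, n = 3 each; exact permutation p = 0.6). The gland list had a median of -0.60 (camera adjusted p = 0.477), with Obp1a at 2.23 (SE 1.01; 82.7 CPM in pup exposure replicate 3 and at most 14.0 CPM in the other libraries), Muc5b at -1.93 (SE 1.0), Bpifb3 at -1.65 (SE 0.90) and Lcn11 at -0.90 (SE 0.61). With single libraries left out the gland median ran from -1.06 to -0.040, and the list passed without control exposure replicate 2 (-0.76, camera adjusted p = 0.00848). With sample quality weights the median turned to 1.13 and Muc5b to 0.92. Without control exposure replicate 3 Muc5b was at -1.05 and Lcn11 at -0.25.

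None of the 4 neuronal marker lists of the organ passed camera. Markers of mature vomeronasal neurons had a median of 0.25 (camera adjusted p = 0.411), with the calcium-activated chloride channels Ano2 (1.07, SE 0.36) and Ano1 (0.68, SE 0.35) and the olfactory marker protein Omp (-0.19, SE 0.38, turning to 0.037 with library totals only). Apical markers had a median of 0.47 (camera adjusted p = 0.200), among them the G protein Gnai2 (0.69, SE 0.44) and Efna5 (1.55, SE 0.68). Without pup exposure replicate 1 Gnai2 was at 0.16, without pup exposure replicate 2 Efna5 was at 0.66 and the apical median at 0.27, and without control exposure replicate 3 that median was 0.26. Basal markers had a median of 0.58 (camera adjusted p = 0.357), among them Gnao1 (0.58, SE 0.40) and Kirrel3 (0.73, SE 0.41), and their median, like Gnao1, was at 0.34 without control exposure replicate 1 and at 0.39 without pup exposure replicate 1. Progenitor and immature neuron markers had a median of -0.014 (camera adjusted p = 0.612). That sign flipped with library totals only (0.39), with limma-voom (0.096), and without control exposure replicate 3 (0.072) or pup exposure replicate 3 (0.17). Stmn1 (-1.11, SE 0.37) and Gap43 (-1.22, SE 0.44) were nevertheless lower in every pup exposure library than in every control exposure library.

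The other lists did not pass with all 6 libraries and TMM factors. Camera adjusted p was 0.0718 for olfactory receptors (median -0.98), 0.923 for vomeronasal receptor pseudogenes (0.20), 0.625 for main olfactory epithelium neurons (0.24, with Rtp1 at 0.89) and 0.234 for blood vessel and smooth muscle cells (0.53, with Tagln at 0.97). Olfactory receptors passed with library totals only (median -0.83, adjusted p = 0.0136) and without control exposure replicate 2 (-1.15, 0.0185), control exposure replicate 3 (-1.29, 0.00797) or pup exposure replicate 1 (-2.06, 0.0129), while their median was 0.18 without a filter (adjusted p = 0.112). Receptor pseudogenes passed without pup exposure replicate 1 (median 0.50, adjusted p = 0.0455). Camera adjusted p was 0.970 for ribosomal protein genes (median 0.022, but -0.015 with RLE factors), which include Rps6 (log2 fold change 0.25, SE 0.94, but -0.30 without pup exposure replicate 1 and -0.011 after thinning). That median was 0.51 without control exposure replicate 3 (adjusted p = 0.000896), 0.29 without pup exposure replicate 2 (adjusted p = 0.0364) and -0.29 without pup exposure replicate 1 (adjusted p = 0.0777). For genes of the endoplasmic reticulum stress response (median -0.24, Trib3 at -1.33), ensheathing glia and Schwann cells (-0.24, Fabp7 at -1.05) and cartilage and bone cells (-0.23, Col1a2 at -0.23), camera adjusted p was 0.234, 0.550 and 0.569, and each of the 3 medians turned positive with library totals only. The median of the stress genes was -0.50 without pup exposure replicate 1 and -0.084 without pup exposure replicate 2, and Trib3 was at -0.73 without control exposure replicate 1 and -0.89 without pup exposure replicate 1. Single libraries left out also took Rtp1 to 0.49 (pup exposure replicate 2), Tagln to 0.54 (pup exposure replicate 3), Col1a2 to -0.064 (pup exposure replicate 2) and the median of blood vessel and smooth muscle cells to 0.94 (control exposure replicate 3). The median of main olfactory epithelium neurons turned to -0.11 without pup exposure replicate 2. Without TMM factors, that is, with library totals only, the median log2 fold change of all genes was 0.31 against 0.030 with them, and 88.8% of genes with an unadjusted p under 0.05 were higher, against 57.5%. Among 6 tested olfactory receptors Olfr769 was lower adjusted over the list alone, at 25, 27 and 10 counts in the control exposure libraries and 0, 1 and 1 in the pup exposure libraries. No trace amine-associated receptor had enough counts to be tested with the filter on low counts. The 37 mitochondrially encoded genes had 0 counts in every library, so their reads are absent from the deposited counts and nothing can be said of their abundance.

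**Figure D2:**
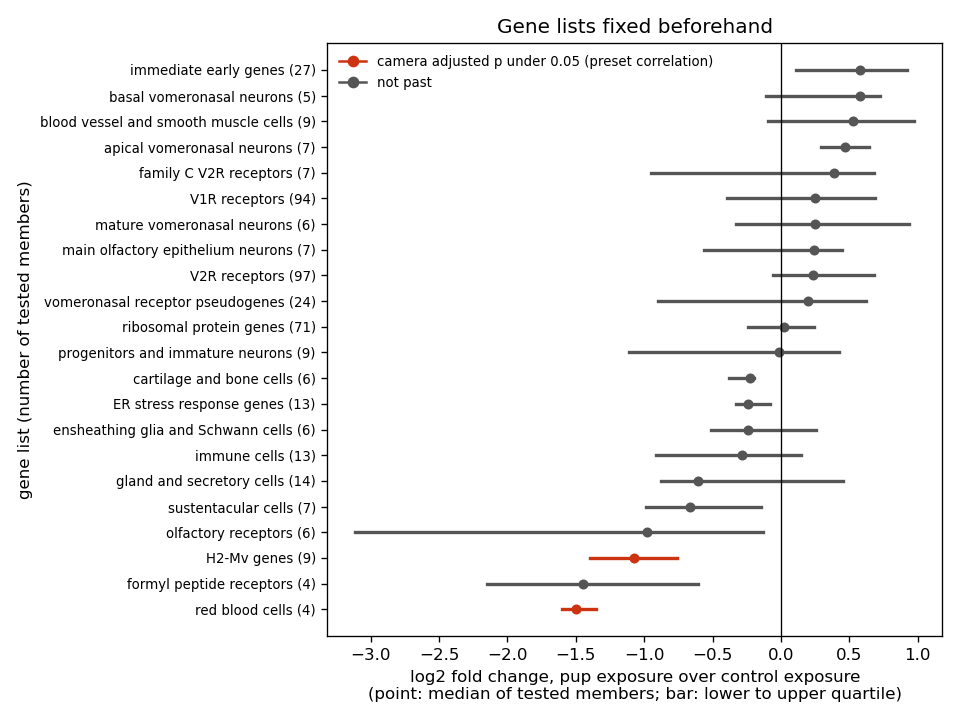
Median log2 fold change (points) and lower to upper quartile (bars) of the tested members of 22 gene lists fixed before the data were examined, pup exposure over control exposure, with the number of tested members in parentheses. Red marks the 2 lists past an adjusted p of 0.05 in camera with the preset correlation, H2-Mv genes (median -1.08) and red blood cells (median -1.50), where both calls are lost with an estimated correlation (adjusted p = 0.524 and 0.487), and several medians near 0 change sign with library totals only.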

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

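The fit on receptors alone, the thinning of every library to the smallest total, the receptor share at an unadjusted p and that in DESeq2 without genes lacking an adjusted p were chosen after seeing the data. Vmn2r116 stayed lower, past the threshold over the receptor list alone, in all 17 alternatives (log2 fold change -4.18 to -3.10), and Vmn2r88 kept its direction in all 17 (2.87 to 3.36) and its call in 16, all but the fit on receptors alone (2.98, adjusted p = 0.0671). Vmn2r65 stayed past the threshold in 12 of 17. The count of 0 genes in each direction over all genes was also found with RLE, upper quartile scaling, library totals only, the stricter filter, thinning and each library left out. Of 292 receptors, 195 had the counts to be tested, with 12999 counts for all receptors in the poorest library. Unless a reason is given, the cause was not tested.

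Without a filter on low counts edgeR called 61 genes higher and 59 lower, 4 receptors higher and 3 lower over all genes, and 8 and 6 over the receptor list alone; the odds ratio of receptors among higher genes was 6.81, the immediate early genes had a median of 0.61 and olfactory receptors turned to 0.18, as more were tested. DESeq2 called 50 genes higher and 77 lower, 5 receptors higher and 2 lower, and 6 and 3 over the receptor list alone, with an odds ratio of 10.8, or 10.43 without genes lacking an adjusted p. Of its calls, 32 higher and 43 lower genes were shared with edgeR without a filter, and its adjusted p was NA for 11599 genes. Limma-voom called 1 gene higher and 7 lower, 1 receptor higher and 1 lower, and with sample quality weights 1 and 11, 1 and 1, and 5 and 2 over the receptor list alone. Each called a single higher gene, Vmn2r88, so the odds ratio had no finite value. With limma-voom the immediate early genes had a median of 0.49, receptor pseudogenes turned to -0.017 and progenitors to 0.096; with quality weights Muc5b turned to 0.92, gland and secretory cells to 1.13 and glia to 0.042.

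With library totals only, 5 lists passed, immediate early genes had a median of 0.86, and signs turned for Col1a2 (0.0099), Arc (0.16), Omp (0.037), endoplasmic reticulum stress genes (0.057), progenitors (0.39), glia (0.26) and cartilage and bone cells (0.012), where the median of all genes was 0.31. With RLE factors ribosomal protein genes turned to -0.015. With an estimated correlation and in fry's directional test 0 lists passed. After thinning, 4 receptors were higher over the receptor list alone and Rps6 turned to -0.011. On receptors alone 0 were called higher.

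Leaving out each library in turn gave 1 to 4 receptors higher and 1 to 2 lower over the receptor list alone, and 1 to 8 lists. Medians ran from 0.33 to 0.71 for immediate early genes, -0.029 to 0.55 for V1R, 0.028 to 0.39 for V2R, -0.22 to 0.65 for family C V2R, -0.29 to 0.51 for ribosomal protein genes, -0.43 to 0.17 for progenitors, -0.72 to 0.18 for glia, -0.38 to 0.050 for cartilage and bone cells, -0.50 to -0.084 for endoplasmic reticulum stress genes, 0.26 to 0.64 for apical and 0.34 to 0.80 for basal markers and -0.11 to 0.66 for main olfactory epithelium neurons. Log2 fold changes ran from -0.40 to 0.33 for Arc and -0.30 to 0.53 for Rps6, and the ratio of formyl peptide receptor shares from 0.288 to 0.788.

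With the replicate number as a block, 0 genes were called in either direction and 2 receptors were higher and 1 lower over the receptor list alone, as without the block; immune cell markers passed camera (adjusted p = 0.0404, 0.00900 to 0.524 over alternatives) and receptor pseudogenes turned to -0.065. Same-numbered libraries had correlations of deviations from the group means of -0.035, 0.18 and 0.075, and the other pairs ones of -0.26 to 0.14. These values show no clear pairing by number, but 3 libraries per group are too few to exclude it.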

Other observations

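Several abundant genes outside the fixed lists were lower in every pup exposure library than in every control exposure library, and were picked here after their values were seen. Clasp2, a microtubule-binding protein, lay at 402, 414 and 383 CPM after control exposure and at 74.7, 93.5 and 63.1 CPM after pup exposure. Nrep lay at 1000, 463 and 390 CPM and at 42.2, 60.2 and 110 CPM. Jup, a protein of cell junctions, lay at 515, 443 and 246 CPM and at 43.6, 94.9 and 113 CPM, and Bcl6, a transcriptional repressor, at 153, 124 and 96.2 CPM and at 3.69, 15.4 and 21.3 CPM. DESeq2 called all 4 lower and limma-voom called Clasp2 (adjusted p = 0.0433) and Nrep (adjusted p = 0.0466) lower. In edgeR none of the 4 was called over all genes (adjusted p = 0.105 for Clasp2, 0.148 for Nrep, 0.191 for Bcl6 and 0.354 for Jup).

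Secreted proteins, also picked after their values were seen, varied between libraries in a way that did not follow exposure. Bpifb1, a secreted protein of airway and nasal glands, lay at 2845 CPM in control exposure replicate 1 and 2088 CPM in pup exposure replicate 3, against 0.895 and 0.156 CPM in the other control exposure libraries and 0.214 and 3.32 CPM in the other pup exposure libraries. Lyz1 lay at 21.7 and 406 CPM in the same 2 libraries, with at most 0.389 CPM in the rest, and Sbpl at 32.7 and 89.7 CPM with 0 counts in the rest. The activity gene Npas4, picked in the same way, was counted in pup exposure replicate 2 alone, with 19 reads.

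Tests of shared words and neighbours, of neuron numbers, and the gene counts in other splits of the libraries were chosen after the results they bear on had been seen. The depth, scaling, ribosomal and remaining split tests were chosen after a first look at the edgeR results too, and only their bounds were written before their own values were seen. Vmn2r88 and Vmn2r65 were higher after pup exposure. After thinning every library to the smallest total, the log2 fold change was 3.11 for Vmn2r88 and 2.85 for Vmn2r65. Thinning keeps the expected share of each gene in a library, so these values could hardly move. They do not decide whether something tied to depth was the cause. With library size and scaling taken from receptors alone the log2 fold change was 2.98 (SE 0.64, against 3.12, SE 0.41, before) for Vmn2r88 and 2.72 (SE 0.57, against 2.88, SE 0.60, before) for Vmn2r65. Both calls ended there, with a prior of 5.37 degrees of freedom in place of 7.90, and the cause of that was not isolated. A rise of all basal neurons would have raised the V2R list, whose median was 0.23 with quartiles of -0.059 and 0.68. Of the words of Vmn2r65, 0.30% were shared, but the bound of 10% written first was missed by Vmn2r88, at 16.6%, and by Vmn2r116, at 13%, so a test of neighbours was added: genes sharing words with Vmn2r88 gained 24.5% as much CPM as Vmn2r88 itself, between the bounds of 10% and 50%, and reads exchanged with relatives cannot be told apart from its own for part of its rise. The neighbours of Vmn2r88 also mix close relatives with unrelated genes that share few words, and only 15 of the 28 were tested. A response of neurons carrying these receptors to pups may account for the pattern and stays a hypothesis.

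Vmn2r116 was lower after pup exposure. After thinning, its log2 fold change was -3.57, which does not decide on depth, as thinning keeps expected shares. Genes that share words with Vmn2r116 changed together by -14.1% of its loss, so no net gain was seen among them. That sum mixes close relatives with unrelated genes that share few words, and only 19 of the 38 genes were tested. A move of reads to single relatives, or to copies that were not counted, was therefore not excluded. A loss of all basal neurons by as much would have lowered Gnao1, whose log2 fold change was 0.58 (SE 0.40), and the V2R list, whose quartiles were -0.059 and 0.68. Some other genes of basal neurons were negative. The H2-Mv genes had a median of -1.08, but their camera call was lost with an estimated correlation (adjusted p = 0.524). Log2 fold changes were -1.69 for Vmn2r7 and -1.37 for Vmn2r6, both with uncertain counts, and -0.39 (SE 0.44) for Tfap2e. Others were positive, with 1.87 for Vmn2r5, 0.97 for Vmn2r3, 0.82 for Robo2 and 0.73 for Kirrel3. Family C had 4 positive and 3 negative members, and the basal markers 3 and 2. A loss of some basal neurons, Vmn2r116 neurons among them, was therefore neither shown nor excluded. What the control exposure was is not described by the labels, and a stimulus in it that drives Vmn2r116 neurons may be the source of the higher control values, which was not tested.

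Many ribosomal protein genes had a low CPM: 32 of 75 lay under 10 CPM, although 71 had the counts to be tested, and Rps6 itself lay at 1.27 ± 0.244 and 1.51 ± 0.837 CPM (SD, n = 3 each). Across these genes, which are not independent replicates, the share of words found in other genes' transcripts and mean CPM had a Spearman rho of -0.295 (permutation p = 0.0104, adjusted 0.0208) and transcript length and mean CPM a rho of 0.0787 (permutation p = 0.500, adjusted 0.500), 2 relations in the family. The first lay just above the bound of -0.3 written in advance, so reads lost to pseudogene copies may explain part of the pattern. Transcript length itself showed no clear relation to CPM. Shared words and length were related to each other (rho -0.43), so a low yield of short transcripts was not fully told apart from reads lost to copies.

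The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes over all genes in each direction, so 10 of 10 splits give as many by construction and that count decides nothing; the highest other gave 2. It gave 2 receptors higher and 1 lower over the receptor list alone, in each case 1 of 10 splits with as many, where the highest other gave 0. It gave 2 lists past the threshold, reached by 8 of 10 splits, and the highest other gave 8, several times the real count. List calls therefore did not set exposure apart, and structure among the libraries that does not follow exposure may produce them. At an unadjusted p under 0.05 in edgeR the real split gave 1701 genes and the others 125 to 811. Ranking highest among 10 splits is the most that this design can show. Depth was separated by the same split, so that count does not tell exposure from depth or from other differences between the groups.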
